A study of Mus musculus with 24 samples.

How the data were processed

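The series holds 24 one-colour Agilent arrays, 1 array per sample. Per the labels, the samples were CD45.1-bearing CD8+ OT-I T cells, which recognise an ovalbumin peptide, taken either from the graft on day 0 (4 samples) or on day 4 after transplantation from blood, liver, lung or intestine of recipients that express ovalbumin in their tissues (5 samples per site). The labels state that recipients were irradiated with 11 Gy in 2 fractions and received bone marrow cells and splenocytes, that only the OT-I cells carried CD45.1, and that they were isolated by magnetic positive selection with an antibody to CD45.1. The labels also state that 300 pg of RNA went through 2 rounds of linear amplification before Cy3 labelling. Mice were female and 8 to 16 weeks old, per the labels. No source used here says that every sample came from its own animal, so p-values measure the spread between these samples.

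The authors deposited 1 Agilent Feature Extraction file per array, whose processed signal is an intensity on a linear scale after background subtraction and detrending, not normalised between arrays. The same deposited files give the mean spot intensity, the median local background intensity and spot flags, the other columns used. The Feature Extraction version is 10.7 per the submitters' processing notes and 9.5.1.1 per the file headers. Each array had 44397 spots, of which 1377 were controls and 43020 measured 39429 different gene probes, with probe coordinates on mm9 per the file headers. The authors also deposited a table of log2 values. Tested on the files, it matched quantile-normalised log2 processed signal with each probe's median over the 24 arrays subtracted, with a lowest correlation of 0.99977 across probes, and it entered only as an alternative.

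Gene names were taken from the annotation of the arrays and updated through the mouse gene table supplied: 27508 probes were named by accession, 3544 by symbol and 404 by synonym. Another 1083 kept the name in the files and 6890 had no symbol. The main values were log2 of the processed signal minus each array's 75th percentile over all gene probes, with control spots and spots marked non-uniform left out and spots of the same probe averaged. A probe was tested if it had a symbol and was well above background, a Feature Extraction flag, on all arrays or all but 1 array of at least 1 group. This left 11209 probes. The probe with the highest mean stood for each gene, which gave 9382 tested genes. In these files 29.9% ± 3.90 (SD, n = 24) of gene probes were well above background.

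A single limma model (limma 3.58.1 in R 4.3.3) was fitted to all 24 arrays with 1 mean per group, and 11 contrasts were drawn from it: each day 4 site against the graft, the equally weighted mean of the 4 sites against the graft, and the 6 pairs of sites. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Simulated data with known changes were drawn independently for 9382 genes, with 1 SD per gene for all groups. On the real arrays the spread was uneven, with a median SD per gene from 0.3 in the graft to 0.606 in intestine. In the simulations the contrast of all sites with the graft recovered 39% of genes changed by 1 log2 unit and 86% of those changed by 2. The simulated contrast of liver with graft recovered 28% and 87%, that of intestine with blood 30% and 77%, and that of lung with liver 40% and 76%.

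The 37 gene lists were written before the data were examined, and 34 of them had at least 5 tested members. They covered T cell function (cytotoxic molecules, cytokines, chemokines, naive markers, activation markers, inhibitory receptors, transcription factors, terminal effector receptors, residency, homing, retinoic acid, T cell identity), cell state (cell cycle, interferon-stimulated genes, interferon gamma-induced genes, glycolysis, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, hypoxia, unfolded protein response, apoptosis, immediate-early genes) and other cells (hepatocyte, lung epithelial, intestinal epithelial, erythroid, neutrophil and monocyte, macrophage, dendritic cell, B cell, CD4 T cell, NK cell, endothelial, mast cell and platelet markers), plus a list of sex-linked genes. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 374 tests, and again with a correlation estimated from the data (statmod 1.5.0). With the estimated correlation 0 of the 120 called list shifts remained past the threshold, so list calls rest on the preset value. The self-contained test fry called 133.

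The rule for genes named in the text was also written before the data were examined. It took the 10 highest and 10 lowest genes called with the same sign in all 4 site contrasts, up to 8 higher and 4 lower genes for each site against every other site, the 5 highest and 5 lowest genes of each tissue against blood, up to 4 called members of each list with the smallest adjusted p plus members that went against their list, and label checks. Genes of the first 3 kinds needed a probe well above background on every array of the higher group, and 1 predicted gene was passed over. The rule named 220 genes. Genes named outside it are said to have been chosen after their values were seen. Where no array of the lower group was well above background, the fold is a lower bound, computed against the dimmest signal called well above background on each array of that group and written "at least".

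Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalisation, centring on the median of the 6496 probes well above background on all arrays, the deposited log2 table, no filter, a filter on all 24 arrays, the mean of a gene's probes, trended and robust variances, array weights, fits of only the groups compared, adjusted p under 0.01, slide and replicate number as blocks, leaving out the other-cell genes from contrasts between sites, and leaving out each array. Alternatives added afterwards were the 75th percentile of probes well above background on all arrays, leaving out population outlier spots, leaving out the other-cell genes from the contrasts with the graft (planned only for those between sites), and leaving out 2 pairs of arrays. The file headers place the arrays on 6 slides and 2 scan days. All 4 graft arrays were on a slide of their own, scanned on another day, while each of the 5 remaining slides held 1 array of every day 4 site. The REML estimation of the array weights gave a warning that it stopped before convergence, and its weights were used as returned. Gene lists were tested with slide as a fixed block only between day 4 sites, and camera was not run with the random blocks that were also planned.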

Results

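Transcripts were measured in CD45.1-bearing CD8+ OT-I T cells before and 4 days after transfer into irradiated mice that express ovalbumin, a mouse setting of acute graft-versus-host disease. There were 4 arrays of the graft on day 0 and 5 arrays each of cells recovered from blood, liver, lung and intestine on day 4. Of the gene probes, 30.4% ± 3.83 (SD, n = 4) were well above background in the graft, 30.03% ± 5.05 in blood, 30.9% ± 1.88 in liver, 28.1% ± 4.16 in lung and 30.3% ± 4.94 in intestine (n = 5 each). The number of arrays limits the precision. Correlations between arrays of a group, across genes that are not independent replicates, ran from 0.938 to 0.973 in the graft, from 0.892 to 0.970 in blood, from 0.872 to 0.977 in liver, from 0.849 to 0.961 in lung and from 0.732 to 0.964 in intestine. The T cell genes Cd8a, Cd8b1 and Cd3e were well above background on all 24 arrays. Cd8a differed between day 4 and graft by 0.32 on the log2 scale (limma adjusted p = 0.487) and Cd8b1 by 0.21 (adjusted p = 0.713), and neither sign was kept under every scaling. Cd3e was 0.81 higher at day 4 (adjusted p = 0.0086), Cd4 had a log2 difference of -0.50 (adjusted p = 0.0327) and Ptprc was not called (-0.51, adjusted p = 0.248). The Cd3e call ended in 2 of 43 alternatives (0.26, adjusted p = 0.182, when arrays were centred on the median of detected probes) and the Cd4 call in 9 of 41, among them each fit without 1 graft array. Ptprc was called lower in 3 of 42, with log2 differences of -1.08 after quantile normalisation and in the deposited log2 table and -1.05 when centred on the median of detected probes (limma adjusted p = 0.00873). None of the sex-linked genes passed the signal filter, so the sex given in the labels was not checked.

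The first principal component held 44.8% of the variance over tested genes and the second 18.2%. The 4 graft arrays lay at -112.27 to -96.76 on the first component, below every day 4 array. Lung 4 and intestine 4 lay apart from the other day 4 arrays.

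**Figure D1:**
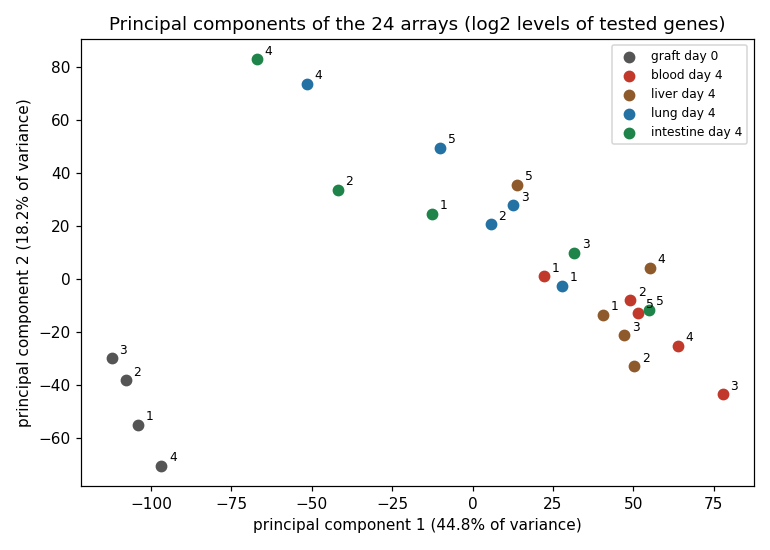
Principal components 1 (44.8% of variance) and 2 (18.2%) of log2 levels of 9382 tested genes, 1 point per array, coloured by group and numbered by replicate. The 4 graft arrays lie to the left of all 20 day 4 arrays, and intestine 4 and lung 4 are nearest to them on the first component alone.

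The comparison of day 4 with the graft asked what changed in the transferred cells after 4 days in the recipients, with the graft cells as the study's control. Samples recovered on day 4 had higher transcripts of the cell cycle, of glycolysis, oxidative phosphorylation and fatty acid oxidation, of cytotoxic molecules and of inhibitory receptors. The lists of naive markers and of immediate-early genes were called lower, with 5 of 18 and 8 of 20 members called lower. Of the 120 list calls in all comparisons, 0 held with an estimated correlation. The lists of B cell, neutrophil, dendritic cell and macrophage genes were called lower at day 4 than in the graft samples, the last with 7 of 15 members called and not in lung. All 4 erythroid genes tested were lower. In none of the lists was a different mix of cells in the graft samples separated from change within the T cells. Of 9382 genes, 5011 were called (3238 higher, 1773 lower), 3369 of them with at least a 2-fold difference.

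Of 32 cell cycle genes, 30 were higher at day 4, 1 was lower and 1 was not called, with the same counts adjusted over the list alone, and the median log2 difference was 2.44 (camera adjusted p = 8.69e-12, and adjusted p = 0.37 with an estimated correlation). These genes encode proteins of DNA synthesis and mitosis. Tk1 was at least 28.7-fold higher (its second probe moved the other way), Rrm2 was 5.39 higher on the log2 scale, Rrm1 3.40 higher and Bub1 at least 3.87-fold higher, each on 20 of 20 day 4 arrays above every graft array. Tyms went the other way, with a log2 difference of -1.19 (limma adjusted p = 0.00233). The list was higher at each site, by a median of 3.08 in blood, 3.02 in liver, 2.29 in lung and 1.68 in intestine.

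Of 14 cytotoxic molecules, 10 were higher, 1 was lower and 3 were not called, or 11 and 1 adjusted over the list alone, with a median log2 difference of 1.02 (camera adjusted p = 0.0349, and adjusted p = 0.659 with an estimated correlation). Granzymes are proteases that T cells release into target cells. Gzmb rose by 7.23 ± 0.571 (SE) on the log2 scale (limma adjusted p = 1.07e-09), Serpinb6b by 5.29 and Fasl by 2.58, while Gzmm had a log2 difference of -4.54. The call of this list ended without graft 3 (adjusted p = 0.0729) and with the filter on all arrays (0.0559). In lung alone it was not called (0.0543). Of 7 cytokine genes, 3 were higher and 1 was lower, Ifng by 5.92 ± 0.6 (limma adjusted p = 4.09e-08) and Il17a by at least 2.26-fold, and the list was not called (camera adjusted p = 0.98). Of 9 chemokine genes, 1 was higher and 2 were lower: Xcl1 was 2.80 higher and Ccl5 had a log2 difference of -1.64 (list adjusted p = 0.264).

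Of 12 inhibitory receptors and exhaustion-associated genes, 9 were higher and 0 lower by limma (9 of 12 also adjusted over the list alone), with a median of 1.73 (camera adjusted p = 0.0194, and adjusted p = 0.525 with an estimated correlation; 0.0502 with array weights). The list was not called in blood alone (0.0686). Lag3 was at least 41-fold higher (limma adjusted p = 6.94e-12), Havcr2 at least 2.18-fold, Pdcd1lg2 at least 3.13-fold and Tox 3.06 higher on the log2 scale, each on 19 or 20 of the 20 day 4 arrays above every graft array. Of 18 activation markers, 9 were higher and 2 lower (list adjusted p = 0.31). Il2ra, a chain of the receptor for interleukin 2, was at least 6.78-fold higher, Icos 4.08 higher and Cd28 3.06 higher. Tnfrsf9 was lower by the probe used (log2 difference -3.42) and higher by the mean of its probes (1.26).

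Of 18 naive and quiescence markers, 0 were higher and 5 lower by limma, and the same 0 and 5 adjusted over the list alone, with a median of -0.37 (camera adjusted p = 0.0292, and adjusted p = 0.659 with an estimated correlation). By site, the list was called in lung (adjusted p = 0.013) and intestine (0.00904) and not in blood (0.0774) or liver (0.133). Under the 5 other scalings 4 to 11 were lower and the median ran from -0.91 to -0.16. Il6ra had a log2 difference of -4.18, Actn1 of -1.48, Klf3 of -1.45 and Txk of -1.31. This call ended with array weights (adjusted p = 0.0592), with the filter on all arrays (0.141), without graft 4 (0.057), without lung 4 and intestine 4 (0.0511), and when each array was scaled to the 75th percentile of probes detected on all arrays (0.0624). Of 20 immediate-early and heat-shock genes, 1 was higher and 8 lower, also adjusted over the list alone, with a median of -0.52 (camera adjusted p = 0.00904, and adjusted p = 0.53 with an estimated correlation). These genes respond within minutes to stimulation or stress. Jun fell by 3.00, Egr1 by 3.03 and Hspa1a by 3.14 on the log2 scale, and Klf6 was 0.77 higher. The call ended with array weights (0.0505) and with the filter on all arrays (0.0863).

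Energy metabolism genes were mostly higher. Of 18 glycolysis genes, 14 were higher and 0 lower by limma, or 15 and 1 adjusted over the list alone, with a median of 1.12 (camera adjusted p = 0.000929, and adjusted p = 0.52 with an estimated correlation): Tpi1 was 2.63 higher, Slc2a1 2.60, Pgk1 1.93 and Hk2 at least 4.78-fold. Of 37 oxidative phosphorylation genes, 28 were higher and 1 lower, or 29 and 1 adjusted over the list alone, with a median of 0.97 (camera adjusted p = 1.49e-05, and adjusted p = 0.659 with an estimated correlation): Uqcrc1 was 2.65 higher, Ndufb8 2.06, Cyc1 1.84 and Ndufa4 1.81, while Ndufa2 had a log2 difference of -0.50. Of 13 fatty acid oxidation genes, 12 were higher and 1 lower, also adjusted over the list alone, with a median of 1.43 (camera adjusted p = 0.002, and adjusted p = 0.507 with an estimated correlation). Cpt1a, the gate of fatty acid entry into mitochondria, was at least 8.26-fold higher and Acadl 2.69 higher, while Acadm had a log2 difference of -0.89.

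None of the other lists of T cell function and cell state was called as a list by camera. In these, counts higher and lower were 4 and 2 of 16 effector and memory transcription factors, 3 and 1 of 7 terminal effector receptors, 4 and 0 of 7 residency markers, 6 and 4 of 20 chemokine receptors and homing molecules, and 2 and 1 of 5 retinoic acid genes. They were 4 and 9 of 23 interferon-stimulated genes, 4 and 4 of 16 interferon gamma-induced genes, 7 and 0 of 12 cholesterol synthesis genes, 5 and 3 of 10 hypoxia genes, 5 and 3 of 16 genes of the unfolded protein response, 5 and 0 of 17 apoptosis regulators, and 4 and 1 of 15 T cell identity genes. Among the transcription factors, Zbtb32 was 4.31 higher, Bhlhe40 3.34 and Batf 2.17. Ccr9, a receptor used in homing to the gut, had a log2 difference of -2.92, and the integrin chains Itgal and Itgb2 were 1.40 and 1.47 higher. Asns was 5.31 higher, Isg15 had a log2 difference of -1.74 and Ifih1 was at least 3.03-fold higher.

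Genes of other cell types were measured in the graft samples, although the labels describe selected CD45.1 cells. Of 18 B cell and plasma cell genes, 0 were higher and 16 lower at day 4 by limma, also adjusted over the list alone, with a median of -5.17 (camera adjusted p = 1.5e-13, and adjusted p = 0.104 with an estimated correlation). Ms4a1, a B cell surface gene, was at least 84.7-fold lower (limma adjusted p = 1.71e-13) and Spib at least 12.8-fold lower, on 4 of 4 graft arrays above every day 4 array. Of 18 neutrophil and monocyte genes, 1 was higher and 14 lower, with a median of -3.36 (adjusted p = 6.81e-09, and adjusted p = 0.0715 with an estimated correlation): S100a8 fell by 7.66. Of 13 dendritic cell and MHC class II genes, 0 were higher and 10 lower (median -2.56, adjusted p = 8.9e-05, and adjusted p = 0.37 with an estimated correlation), H2-Aa by a log2 difference of -5.08. Of 15 macrophage genes, 0 were higher and 7 lower (median -1.84, adjusted p = 0.00299, and adjusted p = 0.621 with an estimated correlation; 0.0618 when arrays were centred on the median of detected probes). In lung it was not called (median -0.49, adjusted p = 0.163). The 4 erythroid genes had a median of -4.41. Of 9 NK cell genes, 1 was higher and 5 lower (median -1.57, adjusted p = 0.0452, and adjusted p = 0.42 with an estimated correlation), a call that other scalings ended and that by site was present in intestine alone (0.0318). Counts higher and lower were 1 and 2 of 5 hepatocyte, 2 and 2 of 8 lung epithelial, 0 and 0 of 9 intestinal epithelial, 1 and 2 of 8 CD4 T cell, 2 and 1 of 9 endothelial and 3 and 2 of 7 platelet genes, and none of these lists was called. The erythroid list and that of mast cells, eosinophils and basophils (1 and 2 of 3 genes) had too few tested members for a list test, which needed 5.

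Among genes called in all 4 sites, the naming rule took 10 that were higher at day 4. Of these, Gzmb (7.23), Ifng (5.92), Cdc20 (5.83) and Ccna2 (5.72) were well above background on 1 or 2 of the 4 graft arrays. The other 6 were not well above background on any graft array and have only bounds without an order: Lag3, Tk1, Ncaph (at least 19.4-fold), Mt2 (at least 22.1-fold), Dut (at least 15.8-fold) and Hmgb3 (at least 20.4-fold). Of the 10 lower genes it took, Ms4a1 has only its bound, and Cd79a, Camp, S100a8, Fcmr, S100a9, Il1b, Ly86, Plbd1 and Hba-a2 had log2 differences from -7.97 to -5.85. Many of these differences rested on probes measured on part of the lower group. Graft arrays well above background were 1 of 4 for Asns, Fasl and Rrm2, 2 of 4 for Acadl and Slc2a1, and 3 of 4 for Bhlhe40, Tox, Tyms and Zbtb32. Day 4 arrays were 1 of 20 for Fcmr, 2 for H2-Aa, 3 for Plbd1, 4 for Actn1, Cd79a and Tyms, 5 for Hspa1a, Il1b and Ly86 and 6 for Camp and Hba-a2. They were 9 for Gzmm and S100a8, 11 for Ccr9, 12 for Il6ra, 13 for S100a9, 15 for Klf3, 16 for Acadm, 17 for Txk and 19 for Cd4 and Ptprc. In mm9 coordinates, the Gzmb probe lies on chromosome 14 from 56877916 to 56877975, the Lag3 probe on chromosome 6 from 124854570 to 124854866 and the Ms4a1 probe on chromosome 19 from 11325367 to 11325426. Of 153 named gene results against the graft, label checks included, 119 kept direction and side of the threshold under every alternative in which they were tested (41 to 43 each).

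The graft arrays shared 1 slide and scan day that held no day 4 array, so the slide and the group cannot be told apart in these comparisons, and no within-slide value exists. The share of higher genes also depended on the scaling. The 75th percentile over all gene probes lay 0.34 higher in the graft, relative to that of probes detected on all arrays, against 0.01 in blood, 0.05 in intestine, -0.18 in liver and -0.15 in lung. Of the called genes, 64.6% were higher in the values reported here, 71.3% (3446 higher, 1384 lower) with normexp background, 50.5% (2546, 2499) after quantile normalisation and 50.5% in the deposited log2 table (2546, 2498). The share was 36.7% (2064, 3560) when arrays were centred on the median of detected probes and 41.1% (2153, 3090) at their 75th percentile. The median of all tested genes moved from 0.23 to -0.31 over these scalings. The cell cycle list kept a median of 1.89 or more, with 27 or more of its 32 genes called higher. Over the 5 other scalings, the median of oxidative phosphorylation ran from 0.43 to 1.05 (19 to 31 of 37 genes higher), of cytotoxic molecules from 0.47 to 1.30 (6 to 10 of 14 higher), of glycolysis from 0.57 to 0.96 (11 to 15 of 18), of fatty acid oxidation from 0.88 to 1.32 (11 of 13 in each), of inhibitory receptors from 1.11 to 1.32 (6 to 9 of 12) and of immediate-early genes from -1.06 to -0.30 (8 to 12 of 20 lower). The median of the effector and memory transcription factors, which were not called as a list, turned from 0.39 to -0.16.

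Per site, 5293 genes were called in blood against the graft (3324 higher, 1969 lower), 4730 in liver (3240, 1490), 3511 in lung (2431, 1080) and 3269 in intestine (2080, 1189). In the scaling that moved the split most, the share of higher genes went from 62.8% to 39.5% in blood, from 68.5% to 36.2% in liver, from 69.2% to 35.5% in lung and from 63.6% to 40.8% in intestine. A total of 2319 genes were called with the same sign at all 4 sites (1636 higher, 683 lower), or 1376 lower and 948 higher at the 75th percentile of detected probes. All sites were compared with the same graft arrays. Simulated unchanged groups, the graft included, gave 0 such genes in each of 50 simulations. They were built from the mean of the graft arrays plus shuffled deviations from the group means. Independent lists would share 66 higher and 5 lower, and with the graft arrays split between the sites 1313 to 1567 were shared. Neither the simulations nor the split can separate a shift common to all graft arrays from a change at the sites. Correlations of the log2 differences between sites, across genes, ran from 0.846 to 0.97, against 0.513 in the simulations. The covariances ran from 1.617 to 2.432, against 0.112 in the simulations. Genes that were called in both sites with opposite signs numbered 3, all between blood and intestine.

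**Figure D2:**
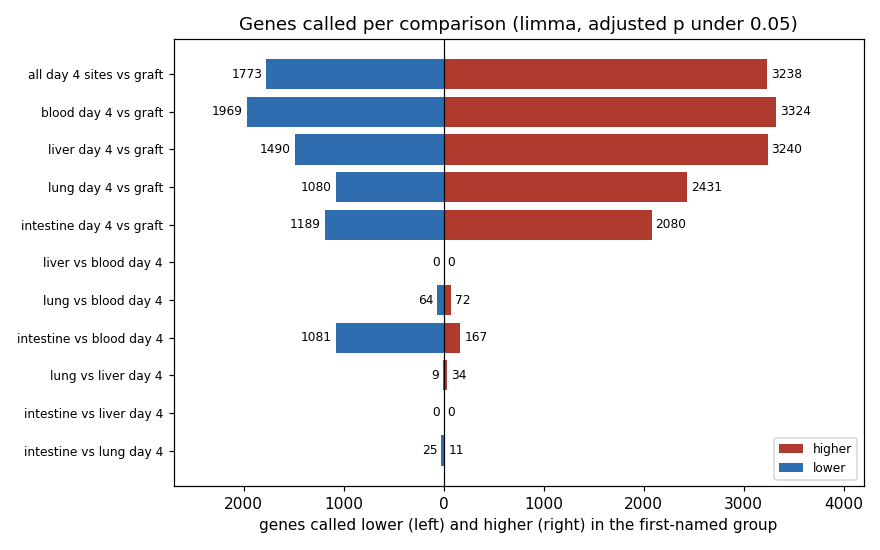
Number of genes called higher (right, red) and lower (left, blue) in the first-named group of each of 11 comparisons, out of 9382 tested (limma, adjusted p under 0.05). The comparisons with the graft have 3269 to 5293 calls and those between day 4 sites 0 to 1248.

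**Figure D3:**
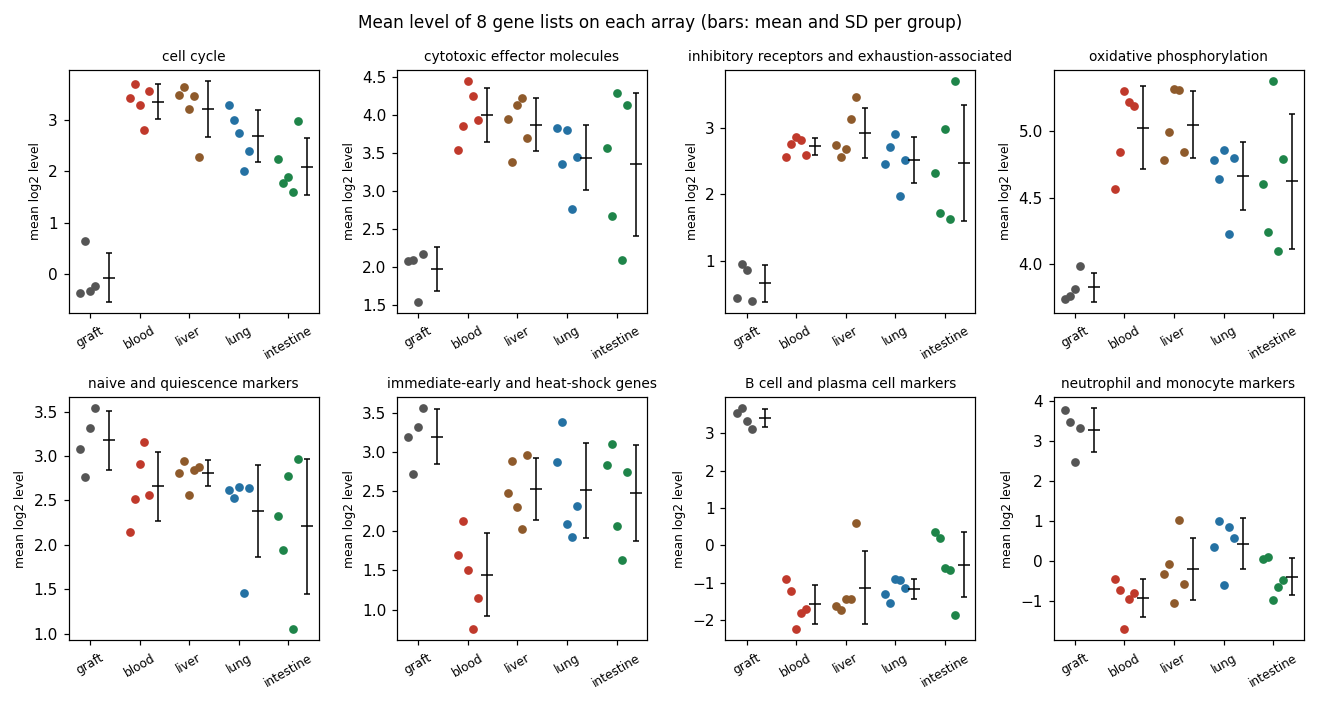
Mean log2 level of 8 gene lists on each array (points, by group), with the mean and SD of each group beside them. Cell cycle levels averaged -0.07 in the graft, 3.36 in blood, 3.21 in liver, 2.69 in lung and 2.09 in intestine.

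The comparisons between sites asked how the cells differed between blood and each tissue on day 4. Intestine had the most calls against blood, although at an unadjusted p under 0.05 lung had more genes (3540 against 3189). The cell cycle list was called lower in intestinal T cell samples, and the lists of immediate-early genes, chemokines and epithelial, dendritic and B cell genes were called higher, each lost with an estimated correlation. Of 9382 genes, 1248 were called (167 higher, 1081 lower), and 905 with slide as a block, each slide holding 1 array of every site. The split was 115 higher and 1089 lower with normexp background, 133 and 580 after quantile normalisation, 168 and 342 when centred on the median of detected probes, and 38 and 127 at their 75th percentile. Without intestine 5 the count was 2926 and without intestine 2 it was 284.

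Of 32 cell cycle genes, 0 were higher and 19 lower in intestine than in blood by limma, or 0 and 26 adjusted over the list alone, with a median of -1.33 (camera adjusted p = 4.8e-08, and adjusted p = 0.507 with an estimated correlation). With slide as a block the camera adjusted p was 7.94e-08, with the filter on all arrays the median was -0.86 (0.00451), and the mean level of the list was lower in intestine on 5 of 5 slides. Ccnb1 and Ccne1, cyclins that time mitosis and entry into DNA synthesis, had log2 differences of -2.33 (limma adjusted p = 0.011) and -2.64 (adjusted p = 0.0117), on 5 of 5 slides each. Aurka and Plk1 had log2 differences of -1.62 and -1.38 (adjusted p = 0.0122 and 0.0117) and were not called at the 75th percentile of detected probes, where 2 of the 32 were. The T cell identity list had a median of -0.57 in the same comparison and was not called (0.135).

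Of 20 chemokine receptors and homing molecules, 2 were higher and 6 lower, or 2 and 8 adjusted over the list alone, and the list was not called (median -0.81, camera adjusted p = 0.158). Fut7, an enzyme that makes selectin ligands, had a log2 difference of -2.05 (limma adjusted p = 0.00442), Itga4 of -1.76 (0.012) and S1pr1, which guides exit into blood and lymph, of -2.69 (0.018), each lower on 5 of 5 slides. The S1pr1 call ended without intestine 2 and without intestine 4. Ccr7 was 1.84 higher on 5 of 5 slides (adjusted p = 0.0238), a call that ended with slide as a block, without intestine 2 and without blood 2. Of 7 residency markers, 0 were called by limma and 2 were higher adjusted over the list alone (median 0.92, camera adjusted p = 0.0184, and adjusted p = 0.37 with an estimated correlation; 0.0712 without intestine 5).

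Of 20 immediate-early and heat-shock genes, 6 were higher and 1 lower, also adjusted over the list alone, with a median of 0.99 (camera adjusted p = 3.88e-05, and adjusted p = 0.37 with an estimated correlation). Fos was 3.44 higher (limma adjusted p = 0.0146) and Dusp1 1.78 higher (0.0119), each on 5 of 5 slides, and the Fos call ended without intestine 2. Of 9 chemokines, 2 were higher and 0 lower, or 4 and 0 adjusted over the list alone (median 0.99, adjusted p = 0.00244, and adjusted p = 0.314 with an estimated correlation). Cxcl10, which interferon gamma induces, was 4.18 ± 0.744 (SE) higher (limma adjusted p = 0.00623) on 5 of 5 slides, and Il17a was 3.47 higher (0.0178), a call that ended without blood 5. The lists of interferon gamma-induced and interferon-stimulated genes had medians of -0.02 and -0.03 in the same comparison. Of 37 oxidative phosphorylation genes, 1 was lower (median -0.40, adjusted p = 0.0232, and adjusted p = 0.83 with an estimated correlation), a call that other settings ended. Of 14 cytotoxic molecules, Prf1 alone was called, with a log2 difference of -2.14 on 4 of 5 slides.

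Genes of other cells moved with these. Of 9 intestinal epithelial and Paneth cell genes, 6 were higher and 0 lower, or 7 and 0 adjusted over the list alone (median 3.96, camera adjusted p = 1e-05, and adjusted p = 0.437 with an estimated correlation). Defa3, a defensin of Paneth cells, was 5.69 higher (limma adjusted p = 0.0125) and Jchain at least 13.5-fold higher (0.0153), both on 4 of 5 slides. On the intestine 5 array Defa3 stood at -1.84 and Jchain at -3.73, near the means of liver 1 to 4 (-1.17 and -2.79), while liver 5 stood at 4.76 and 4.33. Of 13 dendritic cell and MHC class II genes, 2 were higher, or 9 adjusted over the list alone (median 1.57, adjusted p = 2.75e-05, and adjusted p = 0.37 with an estimated correlation), and Cd74 was 4.23 higher. The lists of B cell (3 higher and 1 lower of 18, adjusted p = 0.000954), macrophage (2 higher of 15, 0.000701), endothelial (2 higher of 9, 0.00522), platelet (1 higher of 7, 0.0407) and neutrophil genes (1 higher of 18, 0.043) were also called higher, with adjusted p = 0.528, 0.538, 0.437, 0.542 and 0.574 with an estimated correlation.

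Among called genes well above background on all 5 arrays of the higher group, which leaves out Defa3 and Jchain, the naming rule took Igh-VJ558, Defa23, Iglv1 and Defa27, from 6.14 to 4.41 higher in intestine than in blood, and Defa32, at least 37.9-fold higher, on 4 of 5 slides each. The 5 lower genes it took were Dusp7, Sh2d3c, Cdca2, Fam53b and Fam78a, from -3.89 to -3.28 on 5 of 5 slides each, with Sh2d3c at -3.65 ± 0.556 (SE, limma adjusted p = 0.00442). Blood arrays well above background were 1 of 5 for Cd74, Cxcl10, Defa27, Defa3 and Iglv1, 2 for Fos and Il17a, 3 for Defa23 and 4 for Igh-VJ558. Intestine arrays were 1 of 5 for Cdca2, Dusp7, Fam53b, Prf1 and Sh2d3c, 3 for Fam78a and S1pr1 and 4 for Ccne1 and Defa3. Of 62 named gene results in this comparison, 6 were kept under every alternative in which they were tested (41 to 43 each; Cdca2, Cxcl10, Fam53b, Fam78a, Fut7 and Sh2d3c), and 15 were kept when the stricter threshold and fits of only the groups compared were set aside.

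**Figure D4:**
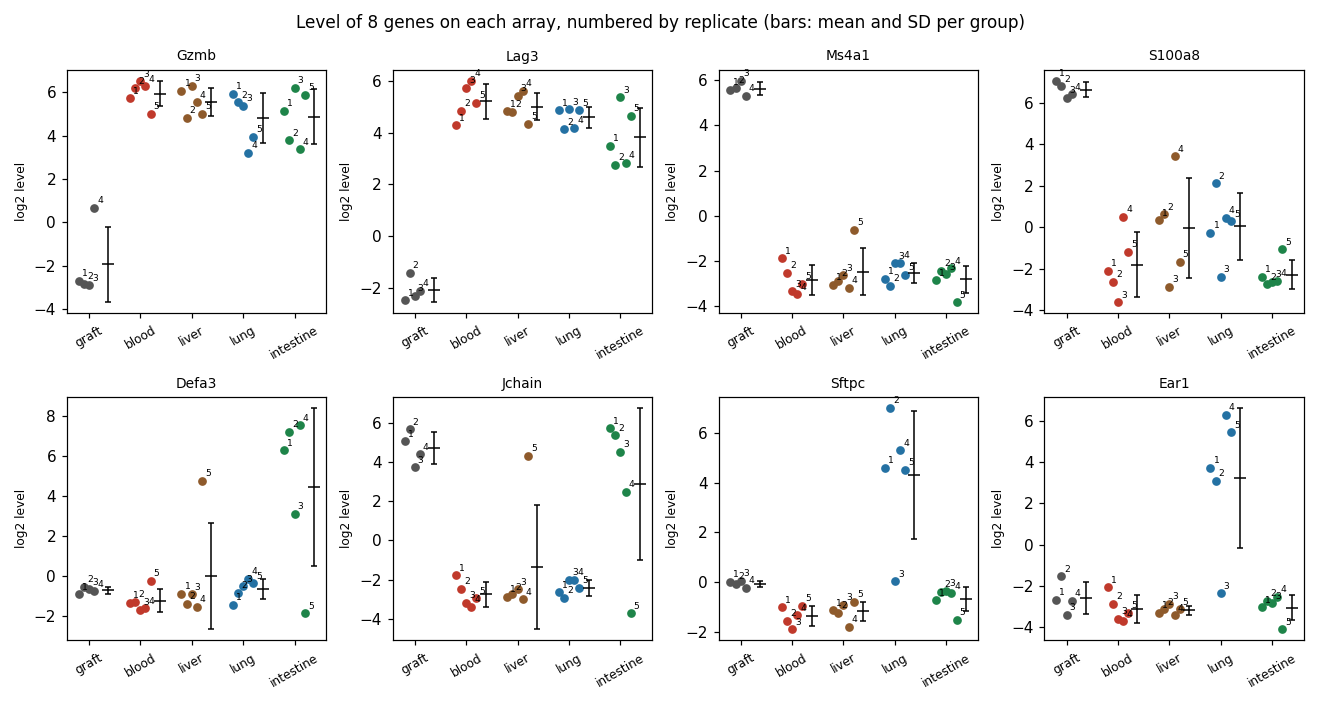
Log2 levels of 8 genes on each array, numbered by replicate, with the mean and SD of each group beside the points. Gzmb and Lag3 lie higher and Ms4a1 and S100a8 lower on all 20 day 4 arrays than on the 4 graft arrays, liver 5 and intestine 5 lie apart from their groups for Defa3 and Jchain, and lung 3 for Sftpc and Ear1.

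The lists of lung epithelium, macrophages and immediate-early genes were among those called higher in lung samples than in blood. Of 9382 genes, 136 were called (72 higher, 64 lower), and 87 with slide as a block. The split was 62 and 146 with normexp background, 47 and 21 after quantile normalisation and 50 and 26 when centred on the median of detected probes. Without lung 1 the count was 1712 and without blood 3 it was 35. Of 8 lung epithelial genes, 4 were higher and 0 lower, or 6 and 0 adjusted over the list alone (median 0.99, camera adjusted p = 3.68e-05, and adjusted p = 0.0904 with an estimated correlation). Sftpc, a surfactant protein, was at least 34.9-fold higher (limma adjusted p = 0.000628) and Sftpd at least 7.65-fold (0.00219), each on 5 of 5 slides. Both were well above background on only 4 of 5 lung arrays and on no blood array, and on lung 3 they stood at 0.045 and -0.667. Of 15 macrophage genes, 2 were higher and 0 lower, or 7 and 0 adjusted over the list alone (median 1.41, camera adjusted p = 3.88e-05, and adjusted p = 0.507 with an estimated correlation): Ear1 was at least 17.6-fold and Ear2 at least 44.2-fold higher. Of 20 immediate-early genes, 3 were higher and 0 lower, or 10 and 0 adjusted over the list alone (median 0.76, adjusted p = 0.000121, and adjusted p = 0.37 with an estimated correlation), with Fos 4.36 higher (limma adjusted p = 0.00987) on 5 of 5 slides.

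The cell cycle list was lower in lung than in blood (median -0.63, camera adjusted p = 0.00407, and adjusted p = 0.721 with an estimated correlation) with 0 of 32 genes called by limma and 0 adjusted over the list alone, and the call ended with the filter on all arrays (0.177). Lists of endothelial (median 1.04, camera adjusted p = 0.000165), neutrophil (0.76, 0.00112), dendritic cell (0.74, 0.00151), intestinal epithelial (0.85, 0.0076), chemokine (0.81, 0.019), hepatocyte (0.58, 0.0318) and platelet genes (0.61, 0.0319) were also called higher. Oxidative phosphorylation (-0.32, 0.0134) and glycolysis (-0.45, 0.0407) were called lower, and none of these held with an estimated correlation. The mean level of the hepatocyte list was 0.86 in the graft, 0.36 in lung, -0.39 in liver, -0.55 in intestine and -1.55 in blood. Its call in lung therefore does not show hepatocytes there. Among called genes well above background on all 5 arrays of the higher group, which leaves out Ear1, Ear2, Sftpc and Sftpd, the naming rule took Fos, Anxa1, Lmna, Dhrs3 and Cavin2, from 4.36 to 2.87 higher in lung than in blood, and Zkscan5, Carm1, Dhx33 and Klhl12, from -2.55 to -2.12, and Cptp, at least 3.27-fold lower. Blood arrays well above background were 1 of 5 for Cavin2, 2 for Anxa1 and Fos, 3 for Lmna and 4 for Dhrs3. Lung arrays were 1 of 5 for Zkscan5, 2 for Carm1 and Dhx33 and 3 for Klhl12. Of 23 named gene results, 2 were kept under every alternative in which they were tested (41 to 43 each; Sftpc and Zkscan5) and 7 when the stricter threshold and fits of only the groups compared were set aside.

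Liver samples had the fewest calls against blood. By limma 0 genes were called, with 302 at an unadjusted p under 0.05, and 4 with slide as a block. Of 20 immediate-early and heat-shock genes, 0 were called and 8 were higher adjusted over the list alone, with a median of 1.05 (camera adjusted p = 2.41e-12, and adjusted p = 0.0715 with an estimated correlation), a call kept under each of the 41 other alternatives run. Lists of residency markers (median 0.77, camera adjusted p = 0.00289), hepatocyte genes (0.64, 0.00448) and neutrophil genes (0.38, 0.00737) were called higher and those of cholesterol synthesis (-0.19, 0.0292) and cell cycle (-0.17, 0.0433) lower, with 0 of their genes called by limma, and with adjusted p = 0.279, 0.0953, 0.474, 0.437 and 0.818 with an estimated correlation. The mean level of the hepatocyte list was lower in liver (-0.39) than in lung (0.36) and the graft (0.86), so its call does not show hepatocytes in liver samples. The cell cycle call ended with slide as a block (0.0662), and without liver 5 its median turned to 0.065.

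Between tissues, 43 genes were called in lung against liver (34 higher, 9 lower), 36 in intestine against lung (11 higher, 25 lower) and 0 by limma in intestine against liver, with 2149 at an unadjusted p under 0.05. With slide as a block these counts were 14, 3 and 0. The splits were 24 and 2 in lung against liver at the 75th percentile of detected probes, and 38 and 38 after quantile normalisation and 33 and 13 at that percentile in intestine against lung. Without liver 5 and intestine 5, intestine against liver had 1814 calls, without intestine 5 alone 1346, without intestine 3 alone 657 and without liver 5 alone 465. Without lung 1 the count in lung against liver was 104, and without intestine 5 that in intestine against lung was 179. Camera called 11 lists in lung against liver, 12 in intestine against liver and 7 in intestine against lung, and only some of them are given here. The cell cycle list was called lower in intestine than in liver (0 of 32 genes called, 23 lower adjusted over the list alone, median -1.08, camera adjusted p = 2.33e-09, and adjusted p = 0.437 with an estimated correlation). It was also called lower than in lung (0 of 32 called, also adjusted over the list alone, median -0.57, adjusted p = 5.83e-06, and adjusted p = 0.542 with an estimated correlation). The T cell identity list was also called lower in intestine than in liver (0 of 15 called, median -0.73, adjusted p = 0.00175, and adjusted p = 0.659 with an estimated correlation). In the same comparison lists of other cells were called higher in intestine: intestinal epithelial (median 2.77, camera adjusted p = 5.39e-07), dendritic cell (1.57, 8.68e-07), macrophage (0.85, 4.75e-06), B cell (0.29, 0.00165), endothelial (0.46, 0.00257) and platelet genes (0.31, 0.0311), with adjusted p = 0.37, 0.279, 0.437, 0.545, 0.42 and 0.525 with an estimated correlation. The lung epithelial list was called higher in lung than in liver (3 of 8 genes, median 0.67, adjusted p = 7.61e-07) and intestine (3 of 8, median -1.12 for intestine against lung, adjusted p = 6.85e-07), both with adjusted p = 0.0715 with an estimated correlation, and Sftpc was at least 36.3-fold and 30.7-fold higher. The list of the unfolded protein response was called higher in intestine than in lung (1 of 16 genes called, median 0.40, adjusted p = 6.29e-07, and adjusted p = 0.279 with an estimated correlation), with Herpud1 1.99 higher (limma adjusted p = 0.0285), a call that ended with slide as a block. The mean level of the unfolded protein response list was 3.24 in intestine, 3.24 in liver, 3.12 in blood and 2.76 in lung, so lung was the low site. The lists of B cell and plasma cell genes (median 0.18, camera adjusted p = 0.0121) and of intestinal epithelial and Paneth cell genes (0.81, 0.00998) were called higher in intestine than in lung, each with adjusted p = 0.659 with an estimated correlation. Fut7 had a log2 difference of -1.74 in intestine against lung (limma adjusted p = 0.0149) on 5 of 5 slides, which also ended with slide as a block.

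By limma, 16 genes were higher in lung than at each other site and 0 were lower, and blood, liver and intestine had 0 of either kind. None of the 16 met the part of the naming rule for sites, since each was well above background on only 4 of the 5 lung arrays. They included Ear1 and Sftpc. On lung 3 Sftpc stood at 0.05 and Ear1 at -2.36, below the lowest other lung arrays at 4.51 and 3.09. Over all sites, such genes numbered 6 with slide as a block (3 higher in lung and 3 lower in blood) and 8 without lung 5, all higher in lung. Without intestine 5 they numbered 139, of which 19 were higher in lung, 35 higher in intestine and 85 lower in intestine. The count for lung was 0 with the filter on all arrays and 0 in fits of only the groups compared.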

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

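In this part all tests of explanations and all counts over other splits of the arrays were chosen after the results were seen, and so was the difference between sites for Poc1b; the rule on arrays apart from their group was set before the data were examined.

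An array was counted as apart when its gap to the nearest array exceeded Dixon's 95% critical share of the group's range, which chance gives in about 1 in 20 groups. Of 20 groups of signal measures 0 had such an array, of 170 groups of list levels 11, and of 459 groups of levels of genes named in the text 35. In lists, the shares were 0.846 for cytotoxic molecules (graft 3 low), 0.904 for naive markers (lung 4 low), 0.85 for activation markers (graft 3 high), 0.992 for homing molecules (graft 4 high), 0.877 for the cell cycle (graft 2 high) and 0.844 for hypoxia genes (graft 2 low). Lung 4 was also low in hypoxia genes (0.754), and liver 5 was high in genes of the unfolded protein response (0.806), the intestinal epithelium (0.899), dendritic cells (0.727) and B cells (0.867).

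Among genes, liver 5 was apart in 14 groups. It was low for Aurka (0.905), Cd8b1 (0.787), Cdc20 (0.851), Cdca2 (0.816), Cyc1 (0.715), Fam53b (0.742), Fam78a (0.819), Plk1 (0.768) and Zbtb32 (0.861), and high for Defa23 (0.953), Defa27 (0.889), Defa3 (0.894), Iglv1 (0.772) and Pdcd1lg2 (0.73). Intestine 5 was high for Cyc1 (0.776) and Hmgb3 (0.864) and low for Igh-VJ558 (0.882). Intestine 4 was low for Dhx33 (0.737), Havcr2 (0.712) and Herpud1 (0.748), and intestine 3 was high for Ndufb8 (0.795). Lung 4 was low for Acadl (0.812), Cd8a (0.731), Cdc20 (0.744) and Dut (0.775), and lung 3 was low for Cd74 (0.744), Ear2 (0.757) and Lmna (0.735). In the graft, array 2 was high for Aurka (0.907) and Plk1 (0.9) and array 4 for Cd3e (0.911) and Klf3 (0.833). Liver 3 was low for Dusp1 (0.743), blood 5 for Lmna (0.746) and blood 1 for Ncaph (0.738).

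Genes called in opposite directions against the graft in blood and intestine were Fam53b, Fut7 and Poc1b. Fam53b was 1.51 higher in blood and had a log2 difference of -1.80 in intestine, and the difference between the sites, tested by limma, was -3.31 (adjusted p = 0.00442). Fut7 was 0.81 higher in blood and at -1.24 in intestine, with a difference of -2.05 (0.00442), and Poc1b was 1.12 higher and at -0.96, with a difference of -2.08 (0.00499). Probes without a gene symbol, which the comparisons left out, also changed: of 2067 such probes that passed the signal filter, 1235 were called between day 4 and graft (585 higher, 650 lower).

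Liver 5 and intestine 5 were out of place. On a scale where the mean of liver 1 to 4 is 0 and that of intestine 1 to 4 is 1, liver 5 stood at 0.922 and intestine 5 at -0.128 in 9 intestinal epithelial genes, at 0.526 and -0.094 in 262 genes that were higher in intestine 1 to 4 than in liver 1 to 4 (other-cell lists left out), and at 0.585 and 0.149 in 1517 that were lower. Intestinal material in liver 5 alone would leave intestine 5 near 1, and its highest position was 0.149, which argues against it. An exchange of the samples or labels is a candidate explanation, although intestine 3 also lay between the groups (0.384 in the epithelial genes) and the larger gene sets were defined on the other 8 arrays. Uneven carry-over into both samples with correct labels cannot be told apart from it, because the hepatocyte genes that would mark liver differed by only 0.092 between liver 1 to 4 and intestine 1 to 4 against an SD of 1.12 within intestine. The arrays were kept as labelled, and no biological explanation was tested.

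Other-cell transcripts were higher in the graft. Of 53 tested members of the B cell, neutrophil, dendritic cell and erythroid lists, 44 were called lower at day 4 and 46 were well above background on all 4 graft arrays. Cells of these types in the graft samples are a candidate explanation. The counts come from the same data as the pattern and restate it, so they do not test that explanation. Selection for CD45.1 would remove such cells only where they lack CD45.1. The labels state that the OT-I cells alone carried it, and whether the other cells did was not tested. Scaling of the arrays was argued against, since at least 42 of the 44 members called lower stayed so under each of the 5 other scalings. The slide and scan day of the graft arrays cannot be told apart from the group, since 0 slides held both. A loss of such transcripts by the T cells themselves was not tested.

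The cell cycle list was lower in intestine than in blood. Its level was 2.09 ± 0.547 (SD) in 5 intestine arrays and 3.36 ± 0.345 in 5 blood arrays (exact two-sided permutation p = 0.0159), lower on 5 of 5 slides. Scaling was argued against by a median of -1.066 or lower under each of the 5 other scalings, and 1 or 2 unusual intestine arrays as the whole cause by a median of -0.894 or lower without each of the 10 pairs of intestine arrays. Other cells that dilute the RNA of intestine samples could lower every T cell transcript: the T cell identity list was at 4.70 ± 0.885 in intestine and 5.26 ± 0.177 in blood (p = 0.23), and the cell cycle level minus the identity level had an exact permutation p of 0.0873, with 0.0079 the smallest possible. This permutation did not pair arrays by slide. By slide, the level minus identity was lower in intestine on 4 of 5 slides and identity itself on 3 of 5. On the slides of arrays 3 and 5 identity was higher in intestine (0.244 and 0.283) while the cell cycle was lower (-1.412 and -0.573). The permutation p misses the threshold without showing that the lists moved alike, so dilution cannot be told apart from slower cycling of intestinal T cells, which stays open.

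Counts were also compared with 100 splits of the same arrays into groups of the same sizes, the real one included, in fits of those arrays alone. The splits and shuffled labels moved arrays freely across slides, although each day 4 slide held 1 array of every site. The real split of all sites against the graft gave 4588 calls and the highest other 2299, blood 6014 and 5301, liver 5592 and 2694, lung 3744 and 2971, and intestine 2434 and 2364. In each, only the real split reached its own count. That makes chance unlikely without excluding it, since 1 of 100 is the smallest share these splits can give. For lung against blood the values were 25 and 9 (1 split), and for intestine against blood 157 and 270, where 2 splits were as large and the other one put blood 1 and 2 together with intestine 1, 2 and 4. For liver against blood the real count was 0 and the highest other 1, for lung against liver 0 and 2038, for intestine against liver 0 and 614, and for intestine against lung 0 and 286, with 100 of 100 splits as large. A real count of 0 is reached by every split, so these splits decide nothing, and chance was not tested for the 43 and 36 calls of lung against liver and of intestine against lung in the fit of all arrays. The splits with 2038 and 614 calls point to a structure of the samples that the sites do not follow: the first put liver 1 to 4 with lung 1, and the second liver 1 to 4 with intestine 5. With all group labels shuffled, 2319 genes common to the sites compared with 0 at most otherwise (1 of 100), and 120 list calls with 121 (3 of 100). For genes higher or lower at 1 site, only the site labels of the 20 day 4 arrays were shuffled, in a fit of those arrays. The real count of 9 compared with 1 at most otherwise (1 of 100).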

How the results depend on the processing

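The alternatives chosen after the data were seen were the 75th percentile of probes detected on all arrays, population outlier spots left out, other-cell genes left out of contrasts with the graft, and the 2 pairs of arrays left out; all others were fixed before. Alternatives that changed none of the counts by over 1.5 times were trended and robust variances, the mean of a gene's probes and population outlier spots. For each count that moved, the cause was not tested except where named.

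With normexp background, the counts were 208 for lung against blood, 13 for lung against liver, 19 for intestine against lung and 10 for genes specific to 1 site. Quantile normalisation and the deposited log2 table each gave 68 for lung against blood, 713 for intestine against blood, 27 for lung against liver and 76 for intestine against lung. Centred on the median of detected probes, the counts were 76, 510 and 59 for lung against blood, intestine against blood and intestine against lung. At the 75th percentile of detected probes they were 52 for lung against blood, 165 for intestine against blood and 26 for lung against liver. Without a filter, liver against blood had 3 calls, intestine against blood 571, and 187 list shifts were called.

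With the filter on all 24 arrays, which tests fewer genes, the counts were 2429 for all sites against the graft, 2405 for blood, 2304 for liver, 1982 for lung, 1725 for intestine and 1237 for genes common to the sites. The same filter gave 2 for liver against blood, 0 for lung against blood, 754 for intestine against blood, 0 for lung against liver, 11 for intestine against lung, 0 for genes specific to 1 site and 43 list shifts.

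Array weights gave 6178 for intestine against the graft, 12 for liver against blood, 688 for lung against blood, 4842 for intestine against blood, 529 for lung against liver, 4343 for intestine against liver, 1372 for intestine against lung, 3792 common genes and 1086 specific to 1 site. The estimation of these weights stopped before it reached its convergence tolerance, so these counts rest on weights that are not final. Fits of only the groups compared, which hold fewer arrays, gave 25 for lung against blood, 157 for intestine against blood and 0 for lung against liver, for intestine against lung and for genes specific to 1 site. At an adjusted p under 0.01 the counts were 2326 for lung and 2100 for intestine against the graft, 23 for lung against blood, 30 for intestine against blood, 14 for lung against liver, 6 for intestine against lung, 1492 common and 6 specific to 1 site. Leaving out other-cell genes gave 25 for lung against liver. Camera with an estimated correlation called 0 list shifts, and fry 133.

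The day 4 arrays share numbers across sites, and each number is also a slide. Pairing would need a correlation over 0.1 in every pair, and 18 of 30 had it. Deviations from the group means correlated by 0.115 on average over equal numbers (-0.37 to 0.564) and by -0.028 over other numbers, and 8 of 20 arrays were closest to an array of their own number. A link through the number or slide is thus not excluded, and the samples were treated as sharing only a number. With the slide as a block, and equally with the replicate block, liver against blood had 4 calls, lung against blood 87, lung against liver 14, intestine against lung 3 and genes specific to 1 site 6. Of 61 list calls between sites, 59 were kept with slide as a block. In contrasts with the graft the slide entered as a random effect, which cannot separate it from the group, so no blocked value is given there. With the replicate block as a random effect these were 2 for liver against blood, 284 for lung against blood, 67 for lung against liver and 60 for intestine against lung.

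Without liver 5 and intestine 5, the counts were 435 for lung against blood, 3006 for intestine against blood, 76 for lung against liver, 1814 for intestine against liver, 259 for intestine against lung and 212 for genes specific to 1 site. Without lung 4 and intestine 4 they were 41 for lung against blood, 646 for intestine against blood, 20 for lung against liver, 2 for intestine against liver, 20 for intestine against lung and 10 for genes specific to 1 site. Leaving out each array in turn gave 0 to 2 for liver against blood, 35 to 1712 for lung against blood, 284 to 2926 for intestine against blood, 18 to 104 for lung against liver, 0 to 1346 for intestine against liver, 9 to 179 for intestine against lung and 8 to 139 for genes specific to 1 site.

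The tested direction turned for Cd8a (-0.13 after quantile normalisation, -0.227 centred on the median of detected probes, -0.117 in the deposited table, -0.093 at the 75th percentile of detected probes), for Cd8b1 (-0.24, -0.335, -0.241 and -0.202 in the same order, and -0.055 without graft 2, with a range of -0.055 to 0.563 over single arrays left out), for Tnfrsf9 (1.26 with the mean of its probes) and for the cell cycle list in liver against blood (0.065 without liver 5, also when intestine 5 was left out too, with a range of -0.267 to 0.065 over single arrays left out). Medians of called lists also crossed 0 while the direction of the camera test stayed: immediate-early genes against the graft in liver (0.295), lung (0.157) and intestine (0.052) with the filter on all arrays, macrophage genes in intestine against the graft (0.548) with array weights, neutrophil genes in lung against liver (-0.015) with normexp background, B cell genes in intestine against lung (-0.042) without lung 1, and residency markers in intestine against lung, from -0.215 to 0.608 over the alternatives. Of 254 named gene results, 224 kept direction and side of the threshold with normexp background, 219 after quantile normalisation, 210 centred on the median of detected probes, 188 at the 75th percentile of detected probes, 169 in fits of only the groups compared and 155 at an adjusted p under 0.01. Of 120 list calls, 118, 107, 95 and 107 kept theirs under those 4 scalings, and 97 with array weights. The 75th percentile signal was 1.282 times the mean of the negative controls in the graft and 1.358 to 1.535 times at the day 4 sites, so genes of low level were measured close to background.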

Other observations

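The gene families in this part were grouped by symbol after the results were seen, and all their tests were chosen then.

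Of the families of protein synthesis and breakdown, several were called higher at day 4 than in the graft and cytosolic ribosomal proteins were called lower. A family of DNA replication genes was also called higher. Of 72 mitochondrial ribosomal protein genes, 51 were higher and 1 lower, with a median log2 difference of 0.92 (camera adjusted p = 2.83e-06, and adjusted p = 0.69 with an estimated correlation). Of 26 aminoacyl-tRNA synthetase genes, 19 were higher and 3 lower (median 1.30, adjusted p = 0.00102), and of 35 proteasome genes 24 and 2 (median 0.76, 0.000993). Of 44 genes with symbols of translation initiation factors, regulators such as Eif2ak3 and Eif4ebp1 included, 23 were higher and 2 lower (median 0.73, 0.0237). Of 10 DNA replication genes outside the cell cycle list, DNA polymerase subunits included, 7 were higher and 2 lower (median 2.62, 0.0093). None of these held with an estimated correlation. The medians stayed above 0 under each of the 5 other scalings, with lowest values of 0.377, 0.757, 0.218, 0.185 and 1.667, while the median of all tested genes fell to -0.313.

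Cytosolic ribosomal protein genes went the other way, with 4 of 82 higher and 18 lower in the values reported here, and 2 to 12 higher and 7 to 70 lower under the 5 other scalings (median -0.27, camera adjusted p = 0.000526, and adjusted p = 0.72 with an estimated correlation). Their median ranged from -0.817 to 0.002 over the 5 other scalings, so the sign did not hold in each of them. Families tested that were not called against the graft were chaperonin subunits (5 higher and 1 lower of 7, adjusted p = 0.257), mitochondrial solute carriers (12 and 3 of 21, 0.0843) and Rab GTPases (16 and 4 of 33, 0.427).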
